A study of Danio rerio with 12 samples.

How the data were processed

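Liver RNA of 12 male zebrafish treated with 17β-estradiol (E2) at 5 µg/L (18 nM), 3 fish each at 4, 12, 24 and 48 h, was compared with RNA pooled from 15 control livers on Agilent dual-colour arrays. Per the labels, E2 was given in the water from a stock in 50% ethanol and renewed daily, RNA was isolated with TRI reagent, treated fish were labelled with Cy5 and the pool with Cy3. The 12 arrays lay on 4 slides with 3 arrays each, and each slide held 3 of the 4 times.

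The deposited array files hold the intensity of each spot in both channels, which the authors obtained with Agilent Feature Extraction, version 9.5.1.1 per the file headers, as mean signal, median local background and a processed signal after background subtraction and dye normalization. Flags of 0 or 1, per the file headers made by the same software, mark spots that are well above background, saturated or outliers. The deposited series values are log10 ratios of Cy5 over Cy3 that the authors took from the same software, and between 27.2 and 35.0% of them per array are exactly 0. The deposited files of the 48 h arrays lack the parameter block and are rounded to 3 significant digits, and 10 gene names in them had become dates, so probe annotation was taken from an intact file. Of 45220 spots per array 43803 were no controls, from 43603 probes. Probes were matched by transcript to the RefSeq genes supplied for the study, and 21111 probes were matched. A proper symbol was held by 19664 probes of 13254 genes. The gene vtg1 was missing from those genes and kept the name in the file.

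Mean signals were background corrected with normexp at an offset of 50 and normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 and the package data.table, version 1.17.8. The plan made before the data were examined applied normexp to the local backgrounds as deposited. Backgrounds up to 65250 beside some spots drove its fitted mean as low as -1232 in Cy5 and -967.2 in Cy3. Local backgrounds above 2 times the median of the array and channel were therefore replaced by that median, in 1 to 555 spots per array in Cy5 and 0 to 737 in Cy3, after which the fitted means were -14.68 to -1.815 and 18.44 to 34.63. This replacement was chosen after the data had been seen, and both the planned version and replacement above 5 times the median were run as alternatives. Spots with an outlier flag were dropped, saturated spots were kept and spots of the same probe were averaged.

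Probes were tested when Cy5 was well above background on all 3 arrays of at least 1 time or Cy3 on at least 6 of 12 arrays, which left 22035 probes. A limma model with 4 group means, 8 residual degrees of freedom and a prior of 2.71 gave each time against the pool, 4 differences between times (12 and 4 h, 24 and 12 h, 48 and 24 h, 48 and 4 h) and an F-test among the times. P values were adjusted by Benjamini and Hochberg over all tested probes, and a gene was called at an adjusted p under 0.05. Each of 9176 genes with a proper symbol was counted once, by its brightest probe. Where none of the 3 fish or no reading of the pool was well above background, a fold is given as a bound. The pool is a single sample, so tests against it leave out the spread among controls.

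A set of 39 gene lists was written before the symbols on the array were seen, and 38 had at least 3 tested genes. Each was compared with all other genes by camera with a preset correlation of 0.01, and again with the correlation estimated from the residuals. The fry test was run beside it, where one p value asks whether genes move on balance one way and the other whether they change in either direction. Genes of a list were also counted after adjustment over the list alone. The list of leukocytes holds 1 gene that a synonym match brought in by mistake, and it is not named.

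Genes are named by rule. Against the pool these are the 10 largest rises and 10 largest falls that passed with the same sign in 3 fish. Between times these are the 5 largest rises and falls that also had no overlap between fish. For each list up to 4 members with the lowest adjusted p could be named, and vitellogenin and estrogen receptor genes were always followed. Some results that met these rules are not reported here. Genes given only with the signal of the pool were chosen after their values had been seen.

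Alternatives were no background correction, a normexp offset of 16, Agilent processed signals, the series values, median centring without loess, loess followed by Aquantile, no filter, and probes well above background in both channels on all 12 arrays. Further ones kept outlier spots, averaged the probes of a gene, used eBayes with trend and robust settings, array weights, slide as a fixed or random block, a block by fish number, only the arrays compared, a linear trend on log time, a threshold of 2-fold, and the other set tests. Each fish was left out in turn. Camera on differences between times was added after the plan. Recovery was tested on simulated data, where changes of 0.5, 1, 2 and 3 on the log2 scale at 48 h against the pool were called in 20, 70, 96 and 98% of probes, and between 24 and 48 h in 0, 48, 82 and 92%. Of 21835 probes without a simulated change 6 were called at 48 h. The simulated noise was independent between probes, without an error shared through the pool and without dye bias, so this count leaves out false calls from those sources. With dust simulated on 40 spots of every array, a true log2 ratio of 2 came out as 1.9 with replaced backgrounds and as 0.58 without. The real arrays varied, with 1 to 555 spots replaced in Cy5 and 0 to 737 in Cy3, so the simulation does not stand for each of them. No probe sequence was realigned, and time of day was not modelled, since no controls were collected at the later times.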

Results

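Gene expression was measured in livers of male zebrafish, 3 months old, that were immersed in the estrogen 17β-estradiol (E2) at 5 µg/L (18 nM). Livers were taken 4, 12, 24 or 48 h after the start of treatment, from 3 fish per time. Each of the 12 Agilent arrays set RNA of a single treated fish, labelled with Cy5, against RNA pooled from the livers of 15 control fish, labelled with Cy3. Per array, 43.8 to 52.1% of the 43603 probes were well above background in the Cy5 channel and 43.2 to 46.8% in the Cy3 channel. Values are log2 ratios of treated fish over the pool, so a negative value is a lower level in the treated fish, and errors are standard deviations (SD) between fish. After dim probes were left out, 22035 probes were tested with limma, and the counts below cover 9176 genes with a proper symbol. Positions are those of the array's probes on the danRer5 assembly, as the files give them.

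The pool counted as a single control sample, so the tests against it leave out the spread among control fish, and the number of arrays limits the precision. Over 15590 bright probes the median absolute deviation of the log2 signal had a median of 0.43 between fish of the same time and of 0.141 between the repeated readings of the pool. The labels call the control fish untreated in one place and treated with ethanol alone in another. No controls were collected at the later times and the dyes were not swapped, so dye bias and any difference in time of day are part of the ratios to the pool. Differences between times cancel a pool reading and a dye bias that are the same on every array. The pool reading was not the same on some probes, such as that of vtg4. Any difference in time of day between the times does not cancel.

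The comparison at 4 h asked which liver genes already differed from the pool. The largest rises were in genes of vitellogenins, the precursors of egg yolk proteins: vtg1 rose 43.3-fold (log2 5.44 ± 0.92, n = 3), vtg4 27.7-fold (4.79 ± 0.36) and vtg3 24.5-fold (4.61 ± 0.32). Of the other members tested, vtg2 rose by 1.11 on the log2 scale (adjusted p = 0.043 in limma), and vtg5 (0.52) and vtg8 (-0.17) did not pass. The estrogen receptor gene esr1 rose 4.47-fold (2.16 ± 0.68, adjusted p = 0.000535). Many genes of cholesterol synthesis fell, a list call that did not hold with an estimated correlation (adjusted p = 0.159). Transcripts of fdps fell 26.9-fold (-4.75 ± 0.44), of cyp51 24.4-fold (-4.61 ± 1.78), of hmgcs1 23.6-fold (-4.56 ± 1.08) and of hmgcra, the rate-limiting reductase, 21.4-fold (-4.42 ± 2.38). In all, 1701 of the 9176 genes (18.5%) changed, 851 up and 850 down, and 458 of them changed at least 2-fold.

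The other 7 of the 10 largest rises were slc43a1a, an amino acid transporter (4.57 ± 0.73), acsl1b, an acyl-CoA synthetase (3.94 ± 0.78), the retinol-binding protein gene rbp2a (3.76 ± 0.49), casp9, a caspase of apoptosis (3.45 ± 1.38), xbp1, a transcription factor of the unfolded protein response (3.37 ± 0.17), the co-chaperone gene dnajb9a (3.02 ± 1.02) and the choline kinase gene chka (2.87 ± 0.31). Adjusted p values of the 10 rises ran from 4.15e-08 for vtg3 to 0.00038 for casp9. The second probe of rbp2a did not pass at 4 h. The largest falls also held ebp (-4.26 ± 1.12), msmo1 (-4.12 ± 1.16) and mvda (-3.81 ± 0.51) of cholesterol synthesis, the ribonuclease gene rnasel2 (-6.14 ± 0.09) and the complement gene c3b.2 (-5.73 ± 0.31). The class I MHC gene mhc1uba was at least 37.9-fold lower, since the treated fish were not well above background on its probe. The probes of rnasel2, c3b.2 and mhc1uba switched between high and low in fish of a later time.

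Among 26 measured genes of cholesterol synthesis and uptake, 20 fell, none rose and 6 did not pass, and 21 fell when adjusted over the list alone. Their median was -2.40 (camera adjusted p = 2.48e-17, but adjusted p = 0.159 with an estimated correlation). Besides fdps and mvda, lss (-3.53 ± 0.50) and nsdhl (-2.86 ± 0.29) had the lowest adjusted p. Ribosome biogenesis rose, with 45 of 67 genes up and none down (50 adjusted over the list alone). The median was 0.80 (adjusted p = 1.14e-24, and adjusted p = 0.195 with an estimated correlation). Examples were dkc1 (1.90 ± 0.27), nop58 (1.69 ± 0.19) and nifk (1.52 ± 0.09). Cytosolic ribosomal protein genes rose too, 32 of 79 with none down (48 adjusted over the list alone). The median was 0.40 (adjusted p = 6.92e-15, and adjusted p = 0.372 with an estimated correlation). The vitellogenin list itself had 4 of 6 members up, also when adjusted over the list alone. The median was 2.86 (adjusted p = 1.65e-05, and adjusted p = 0.163 with an estimated correlation).

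Chaperones of the endoplasmic reticulum (ER) were lower at 4 h, with 16 of 33 down and 1, dnajb9a, up (17 down adjusted over the list alone). The median was -0.54 (adjusted p = 5.05e-07, and adjusted p = 0.268 with an estimated correlation). Examples were creld2 (-2.12 ± 0.28) and hyou1 (-1.64 ± 0.10). Proteasome subunits had 18 of 33 down and none up (25 down adjusted over the list alone). The median was -0.40 (adjusted p = 2.45e-11, and adjusted p = 0.163 with an estimated correlation), but 0.37 with arrays centred on their medians. Among the falls were psmd8 (-0.84 ± 0.16), psmd4a, psma6a and psmc6, but with that centring the values of psmd4a, psma6a and psmc6 were 0.07, 0.02 and 0.24. DNA replication and cell cycle genes had 13 of 54 down and 1 up (14 and 1 adjusted over the list alone). The median was -0.40 (adjusted p = 0.00021, and adjusted p = 0.816 with an estimated correlation). With local backgrounds as deposited it was -0.11 and not called. The replication helicase genes mcm6 (-2.28 ± 0.53) and mcm3 (-1.66 ± 0.18) were down and the cyclin gene ccnd1 (1.88 ± 0.19) was up. Markers of another tissue moved at the same time: of 30 pancreatic genes 15 fell and none rose (25 down and 1 up adjusted over the list alone). The median was -1.91 (adjusted p = 7.6e-09, and adjusted p = 0.372 with an estimated correlation). Examples were ctrb.2 (-3.15 ± 0.68) and cel.1 (-1.98 ± 0.76). The array medians of this list were -2.45, -1.98 and -0.95 at 4 h.

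At 4 h 6 more lists were called. Oxidative phosphorylation had 2 of 64 genes up and 1 down, none adjusted over the list alone. The median was 0.15 (adjusted p = 0.036, and adjusted p = 0.772 with an estimated correlation). Steroid hormone metabolism had 5 of 16 genes down, also adjusted over the list alone, among them hsd17b7 (-3.31 ± 0.98). The median was -0.40 (adjusted p = 0.00161, and adjusted p = 0.216 with an estimated correlation). With median centring it was 0.05, but the list was still called low against other genes (camera adjusted p = 0.0133). Glycolysis and gluconeogenesis had 6 of 39 down, also adjusted over the list alone. The median was -0.33 (adjusted p = 0.00106, and adjusted p = 0.31 with an estimated correlation), but 0.28 with arrays centred on their medians. Apolipoproteins had 5 of 17 down (6 adjusted over the list alone), led by apoa1b (-1.73 ± 0.30). The median was -0.42 (adjusted p = 0.0095, and adjusted p = 0.209 with an estimated correlation), but 0.37 with median centring. ER translocation and export had 11 of 55 down and 4 up (13 and 4 adjusted over the list alone). The median was -0.17 (adjusted p = 0.00067, and adjusted p = 0.552 with an estimated correlation). Amino acid catabolism had 9 of 61 down and 2 up, also adjusted over the list alone. The median was -0.16 (adjusted p = 0.036, and adjusted p = 0.643 with an estimated correlation). The medians of the last pair were 0.52 and 0.62 with median centring, the former was not called without fish 3 (-0.13) nor the latter without fish 2 (-0.17), and the methionine adenosyltransferase gene mat2aa (2.15 ± 0.73) was up. The share of changed genes that were up was 50% here and 95% when arrays were centred on their medians in place of loess, which gave 3702 changed genes. With that centring the median of all genes was 0.354 at 4 h, 0.166 at 12 h, 0.30 at 24 h and 0.264 at 48 h, against 0.007, 0.007, 0 and -0.023 with loess. The count was 978 without fish 1, 984 without fish 2, 846 from the 3 arrays alone and 658 with local backgrounds as deposited.

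At 12 h more genes differed from the pool. The vitellogenin gene vtg1 rose 252-fold (7.98 ± 0.30), vtg3 94.2-fold (6.56 ± 0.01) and vtg4 by 5.30 ± 0.21 on the log2 scale, while vtg5 rose 2.13-fold (1.09 ± 0.39). Transcripts of esr1 rose 13-fold (3.70 ± 0.81). Cholesterol synthesis genes were still low, with fdps down 21.7-fold (-4.44 ± 0.64) and cyp51 down 27-fold (-4.76 ± 0.82), and DNA replication genes were now high, list calls that did not hold with an estimated correlation. In all, 3090 genes (33.7%) changed, 1629 up and 1461 down, and 1008 changed at least 2-fold. Of the genes up at 4 h, 619 were also up at 12 h, and 522 of those down at 4 h were also down, against 151 and 135 if the lists were independent. Part of that excess may come from the shared control pool.

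The 10 largest rises at 12 h further held rbp2a (5.75 ± 0.31), whose second probe was called in the opposite direction, slc43a1a (4.97 ± 0.23), the kinase gene pim2 (4.83 ± 0.36), acsl1b (4.36 ± 0.35), the transcription factor gene atoh8 (3.95 ± 0.16) and the liver protease gene nots (3.75, 13.4-fold). The synthase gene eevs rose at least 20.3-fold, since the pool was not well above background on its probe. Among the largest falls were rnasel3 (-4.91 ± 0.64), aacs, an acetoacetyl-CoA synthetase (-4.30 ± 0.03), the lipase gene lipg (-4.01 ± 0.98), hmgcs1 (-3.97 ± 1.36) and c3b.2 (-5.44 ± 0.35), and mhc1uba was at least 33.2-fold lower. Both ctsba (-8.07, -7.77 and -0.14) and rnasel2 (-6.36, -6.35 and -1.42) were very low in 2 fish and much less so in the third, but the second probe of ctsba showed the opposite (2.46, 2.44 and -5.88).

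DNA replication and cell cycle genes rose, with 32 of 54 up and none down (34 adjusted over the list alone). The median was 1.24 (adjusted p = 1.82e-14, and adjusted p = 0.397 with an estimated correlation). Here mcm3 was at 2.97 ± 0.31, ccnd1 at 2.77 ± 0.31, mcm6 at 2.61 ± 0.12 and the replication clamp gene pcna at 1.82 ± 0.46. Nearly the whole ribosome biogenesis list rose, 65 of 67, also adjusted over the list alone. The median was 1.26 (adjusted p = 2.86e-31, and adjusted p = 0.153 with an estimated correlation). Examples were mrto4 (2.17 ± 0.17) and polr1e (2.05 ± 0.25). Ribosomal protein genes had 59 of 79 up and none down (68 adjusted over the list alone). The median was 0.58 (adjusted p = 1.97e-18, and adjusted p = 0.266 with an estimated correlation). Translation factors and tRNA synthetases had 15 of 41 up and none down (17 adjusted over the list alone), such as eif6 (1.08 ± 0.17). The median was 0.31 (adjusted p = 0.0012, and adjusted p = 0.457 with an estimated correlation). The vitellogenin list had 5 of 6 up, also adjusted over the list alone. The median was 3.49 (adjusted p = 1.23e-05, and adjusted p = 0.153 with an estimated correlation).

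Cholesterol synthesis and uptake had 21 of 26 down and none up (22 adjusted over the list alone). The median was -2.54 (adjusted p = 1.82e-14, and adjusted p = 0.153 with an estimated correlation). Among the falls was the sterol exporter gene abcg5 (-1.83 ± 0.14). Xenobiotic metabolism had 31 of 66 down and 3 up (37 and 3 adjusted over the list alone), such as ugt1b1 (-1.92 ± 0.19). The median was -0.54 (adjusted p = 8.79e-08, and adjusted p = 0.19 with an estimated correlation). Amino acid catabolism had 29 of 61 down and 5 up (31 and 5 adjusted over the list alone), with csad (-3.46 ± 0.16) and the tryptophan dioxygenase gene tdo2a (-3.37 ± 0.90). The median was -0.43 (adjusted p = 6.55e-06, and adjusted p = 0.224 with an estimated correlation). With median centring it was 0.02, but the list was still called low against other genes (camera adjusted p = 0.0215). In the growth hormone and IGF axis igf2a (-3.05 ± 0.35), igf1 (-1.99 ± 0.38) and the receptor gene ghra (-1.16 ± 0.44) were down and igfbp1b (1.51 ± 1.33) was up. Of the list, 5 of 16 fell and 2 rose (8 and 2 adjusted over the list alone). The median was -0.57 (adjusted p = 0.0373, and adjusted p = 0.19 with an estimated correlation). That list no longer passed without fish 2 (adjusted p = 0.0718).

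Also called down at 12 h were ER chaperones (15 of 33 down and 3 up, 15 and 4 adjusted over the list alone, median -0.37, adjusted p = 0.00679, and adjusted p = 0.518 with an estimated correlation), with pdia4 at -2.80 ± 0.10. With median centring that list was at -0.14 and not called. Proteasome subunits had 12 of 33 down and none up (14 adjusted over the list alone), a median of -0.23 (adjusted p = 0.000234, and adjusted p = 0.266 with an estimated correlation) and 0.21 with median centring. Coagulation genes had 6 of 23 down, also adjusted over the list alone, led by f5 (-1.85 ± 0.30). The median was -0.26 (adjusted p = 0.00486, and adjusted p = 0.425 with an estimated correlation) and 0.34 with median centring. Steroid hormone metabolism had 8 of 16 down and 1 up (10 and 1 adjusted over the list alone), with hsd17b3 (-3.45 ± 0.68) and hsd11b2 (-2.19 ± 0.58), a median of -0.65 and adjusted p = 0.000575 (adjusted p = 0.187 with an estimated correlation). Glycolysis and gluconeogenesis had 13 of 39 down and 1 up (18 and 1 adjusted over the list alone). The median was -0.55 (adjusted p = 0.000251, and adjusted p = 0.224 with an estimated correlation). Apolipoproteins had 7 of 17 down, also adjusted over the list alone. The median was -0.48 (adjusted p = 0.0113, and adjusted p = 0.19 with an estimated correlation), but -0.09 and not called with median centring. The up share was 52.7%, against 82.4% with median centring. With local backgrounds as deposited 1892 genes changed.

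At 24 h vtg1 was 693-fold above the pool (9.44 ± 0.39), rbp2a 184-fold (7.52 ± 0.37, second probe opposite), vtg3 129-fold (7.01 ± 0.32) and vtg4 93.4-fold (6.55 ± 0.35). Transcripts of vtg5 were up 22.2-fold (4.47 ± 0.59) and of vtg2 13.2-fold (3.72 ± 0.53), and vtg8 passed for the first time, at least 2.5-fold higher, the pool being not well above background. DNA replication, ribosome and proteasome genes were high, cholesterol synthesis was no longer low, and coagulation, complement and detoxification genes were low. These are list calls that did not hold with an estimated correlation (adjusted p from 0.105 to 0.424). In all, 4493 genes (49%) changed, 2445 up and 2048 down, and 1753 changed at least 2-fold. Between 12 and 24 h, 1210 genes were up at both times and 903 down at both, against 434 and 326 for independent lists, part of which may come from the shared pool.

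Other large rises at 24 h were eevs (6.11 ± 0.51), acsl1b (4.97 ± 0.15), nots (4.76 ± 0.87), slc43a1a (4.52 ± 0.80) and the acyltransferase gene agpat4 (4.52 ± 0.57), and acsl5 rose at least 21.5-fold. The largest falls held thrsp, a gene of lipid synthesis control (-4.79 ± 0.46), ypel3 (-4.78 ± 0.31), the mitochondrial carrier gene slc25a48 (-4.74 ± 1.28), hsd11b2, which inactivates cortisol (-4.56 ± 0.28), hsd17b3 (-4.21 ± 0.33), the matrix protein gene tgfbi (-4.20 ± 0.18), cbln6 (-4.83 ± 0.96) and the class II MHC gene mhc2dga (-4.55 ± 1.19). Per fish, ctsba stood at -1.07, -8.11 and -7.28. A probe assigned to tapbp.1, a peptide-loading gene, but named mhc1ufa in the array annotation, stood at -7.87, -7.52 and -0.25. The other tapbp.1 probe did not follow it (correlation of deviations -0.03), while the mhc1uea probe was at -5.76, -5.33 and -0.54. Which gene the probe assigned to tapbp.1 reads was not tested. The probe of mhc2dga had switched at 4 h (-0.64, -5.22 and 1.06), and at 24 h those of c3b.2 (-0.55, -0.99 and -5.58) and mhc1uba (2.64, 1.34 and -5.51) did.

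The list of DNA replication and cell cycle had 47 of 54 genes up and none down (53 adjusted over the list alone). The median was 2.25 (adjusted p = 1.13e-19, and adjusted p = 0.193 with an estimated correlation). Here mcm3 was at 3.99 ± 0.50 and cdk2 at 3.75 ± 0.47. Proteasome subunits had turned up, 31 of 33 with none down (31 up and 1 down adjusted over the list alone). The median was 0.86 (adjusted p = 2.38e-12, and adjusted p = 0.105 with an estimated correlation). Transcripts of psmd13 rose by 1.02 ± 0.09. ER translocation, glycosylation and export had 36 of 55 up and 2 down (37 and 2 adjusted over the list alone), with ostc (1.41 ± 0.19) and lman1 (1.33 ± 0.30). The median was 0.64 (adjusted p = 1.07e-08, and adjusted p = 0.157 with an estimated correlation). Ribosome biogenesis had 59 of 67 up, also adjusted over the list alone. The median was 1.27 (adjusted p = 5.31e-21, and adjusted p = 0.114 with an estimated correlation). Ribosomal proteins had 53 of 79 up and 1 down (58 and 1 adjusted over the list alone). The median was 0.49 (adjusted p = 8.45e-10, and adjusted p = 0.328 with an estimated correlation). Translation factors had 25 of 41 up and 1 down, also adjusted over the list alone. The median was 0.70 (adjusted p = 5.91e-07, and adjusted p = 0.169 with an estimated correlation). All 6 vitellogenins rose, also adjusted over the list alone. The median was 5.51 (adjusted p = 4.49e-08, and adjusted p = 0.0838 with an estimated correlation). Cholesterol synthesis now had 12 of 26 up and 3 down (13 and 3 adjusted over the list alone), with fdps at 1.77 ± 0.64 and mvk at 1.71 ± 0.07 but abcg5 at -2.28 ± 0.11 and ldlra at -1.26 ± 0.40. The median was 0.74 (adjusted p = 0.0313, and adjusted p = 0.424 with an estimated correlation). Without fish 1 the list had a median of 0.59 and did not pass (adjusted p = 0.0933).

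Coagulation and complement genes were low at 24 h. Coagulation had 18 of 23 down and none up, also adjusted over the list alone, with f5 (-3.56 ± 0.31), cpb2 (-2.09 ± 0.36) and f10 (-1.41 ± 0.20). The median was -1.37 (adjusted p = 5.37e-09, and adjusted p = 0.112 with an estimated correlation). Complement had 12 of 22 down and none up (13 adjusted over the list alone), with cfhl2 (-3.39 ± 0.32) and c9 (-2.08 ± 0.31). The median was -1.19 (adjusted p = 9.51e-06, and adjusted p = 0.112 with an estimated correlation). Markers of bile duct, endothelial and stellate cells moved with them, 19 of 40 down and 1 up, also adjusted over the list alone. The median was -0.39 (adjusted p = 0.000236, and adjusted p = 0.122 with an estimated correlation). Red cell markers moved with them too, 13 of 28 down and 3 up, also adjusted over the list alone. The median was -0.37 (adjusted p = 0.0193, and adjusted p = 0.424 with an estimated correlation). Intestinal markers were also called low, with values given under other observations. Pancreatic markers had 3 of 30 down and 1 up (1 down adjusted over the list alone). The median was -0.56 (adjusted p = 0.0439, and adjusted p = 0.629 with an estimated correlation), but 0.08 without fish 1.

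Some metabolic lists were low as well. Xenobiotic metabolism had 47 of 66 down and none up (49 adjusted over the list alone), with cyp1a (-2.91 ± 0.32) and ugt1b1 (-2.56 ± 0.32). The median was -1.07 (adjusted p = 3.5e-12, and adjusted p = 0.112 with an estimated correlation). Amino acid catabolism had 43 of 61 down and 7 up (44 and 7 adjusted over the list alone), with bhmt (-3.46 ± 0.37) down and mat2aa (3.63 ± 0.23) up. The median was -0.88 (adjusted p = 1.46e-07, and adjusted p = 0.122 with an estimated correlation). With median centring it was 0.06, but the list was still called low against other genes (camera adjusted p = 0.00637). Fatty acid oxidation had 22 of 36 down and 1, cpt1aa (1.78 ± 0.11), up (24 and 1 adjusted over the list alone). The median was -0.85 (adjusted p = 1.02e-06, and adjusted p = 0.122 with an estimated correlation), but 0.14 with median centring. The growth hormone and IGF axis had 9 of 16 down and none up (10 adjusted over the list alone), with igf1 at -2.73 ± 0.61. The median was -1.24 (adjusted p = 0.000279, and adjusted p = 0.0838 with an estimated correlation). Apolipoproteins had 11 of 17 down and 1 up, also adjusted over the list alone. The median was -0.99 (adjusted p = 0.00159, and adjusted p = 0.112 with an estimated correlation). Glycolysis and gluconeogenesis had 20 of 39 down and 3 up, also adjusted over the list alone. The median was -0.58 (adjusted p = 0.0015, and adjusted p = 0.193 with an estimated correlation), but 0.13 with median centring. The up share was 54.4%, against 87.7% with median centring, and with local backgrounds as deposited 3618 genes changed.

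At 48 h the levels of vtg1 (761-fold, 9.57 ± 0.32), rbp2a (237-fold, 7.89 ± 0.15, second probe not passed), vtg3 (135-fold, 7.08 ± 0.29), vtg4 (127-fold, 6.99 ± 0.45), vtg5 (66.4-fold, 6.05 ± 0.47) and vtg2 (37.3-fold, 5.22 ± 0.64) stood far above the pool, and vtg8 was at least 6.27-fold higher. Genes of cell division had entered the largest rises, with kpna2, an importin, up 116-fold (6.86 ± 0.13), the mitotic cyclin gene ccnb1 58.2-fold (5.86 ± 0.18) and ube2c 45.1-fold (5.50 ± 0.21). The ER isomerase gene fkbp11 rose 46.3-fold (5.53 ± 0.40) and eevs 81.7-fold (6.35 ± 0.23). In all, 4982 genes (54.3%) changed, 2673 up and 2309 down, and 2006 changed at least 2-fold. At both 24 and 48 h, 1917 genes were up and 1558 down, against 712 and 515 for independent lists, part of which may come from the shared pool.

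The largest falls at 48 h held cbln6 (-5.24 ± 0.60), slc25a48 (-5.13 ± 1.05), hsd17b3 (-4.99 ± 0.36), the amino acid transporter gene slc43a1b (-4.85 ± 0.22), hsd11b2 (-4.78 ± 0.33) and the thyroid hormone deiodinase gene dio2 (-4.72 ± 0.54). Transcripts of the MHC gene mhc2d8.35b2 were also low (-5.05 ± 0.45), and so were those of mhc1uba, where only 1 of 3 fish was well above background and the probe is one that switched at 24 h. Per fish, the probe assigned to tapbp.1 stood at -7.51, -7.83 and -0.21 and rnasel2 at -7.21, -6.51 and -1.02. Of the estrogen receptors, esr1 stayed at 3.87 ± 0.27 after 3.88 ± 0.05 at 24 h. The values of esr2a were -0.31 at 4 h and -0.17 at 48 h, neither past the test, and it fell at 12 h (-0.76 ± 0.39) and 24 h (-0.50 ± 0.14), but with median centring it was at 0.30 at 4 h, 0.23 at 24 h and 0.59 at 48 h and its second probe did not pass at any time. The gene esr2b passed at 24 h alone (-0.93 ± 0.86), with values of 0.35, -0.63 and -0.13 at the other times, the last at 0.69 with median centring. The second probe of esr2b passed at 12 h (-0.81) and 24 h (-1.34) and stood at -0.83 at 4 h, opposite to the first.

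DNA replication and cell cycle genes rose in 53 of 54 cases, also adjusted over the list alone, with kif11 (5.02 ± 0.25) and rpa2 (3.29 ± 0.22). The median was 2.65 (adjusted p = 1.03e-21, and adjusted p = 0.173 with an estimated correlation). Proteasome subunits rose in 32 of 33, also adjusted over the list alone, with psmb3 at 1.91 ± 0.21. The median was 0.98 (adjusted p = 1.93e-14, and adjusted p = 0.0588 with an estimated correlation). ER translocation, glycosylation and export had 45 of 55 up and 2 down (47 and 2 adjusted over the list alone), with lman1 (1.90 ± 0.31) and sec11a (1.53 ± 0.16). The median was 1.07 (adjusted p = 1.46e-12, and adjusted p = 0.116 with an estimated correlation). ER chaperones had turned up, 15 of 33 with 4 down, also adjusted over the list alone, with ero1a (3.06 ± 0.14) and fkbp2 (2.67 ± 0.23). The median was 0.42 (adjusted p = 0.00429, and adjusted p = 0.332 with an estimated correlation). At 24 h that list had not been called, with a median of 0.18. The 6 vitellogenins all rose, also adjusted over the list alone. The median was 6.52 (adjusted p = 3.26e-08, and adjusted p = 0.0588 with an estimated correlation). Ribosome biogenesis had 55 of 67 up and 1 down (56 and 1 adjusted over the list alone). The median was 0.92 (adjusted p = 6.87e-14, and adjusted p = 0.158 with an estimated correlation). Ribosomal proteins had 41 of 79 up and 1 down, also adjusted over the list alone. The median was 0.34 (adjusted p = 3.26e-06, and adjusted p = 0.419 with an estimated correlation). Translation factors had 26 of 41 up and 3 down, also adjusted over the list alone. The median was 0.63 (adjusted p = 1.17e-05, and adjusted p = 0.196 with an estimated correlation).

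Lists of coagulation, complement, acute phase and apolipoprotein genes were lower at 48 h. Coagulation had 19 of 23 down and none up, also adjusted over the list alone, including the fibrinogen genes fgg (-2.91 ± 0.13) and fgb (-2.75 ± 0.20) and f5 (-4.19 ± 0.36). The median was -1.72 (adjusted p = 5.58e-10, and adjusted p = 0.0906 with an estimated correlation). Complement had 18 of 22 down and none up (21 adjusted over the list alone), with c9 (-3.04 ± 0.49) and c1r (-2.75 ± 0.24). The median was -1.69 (adjusted p = 1.84e-08, and adjusted p = 0.0588 with an estimated correlation). Acute phase and metal-handling proteins had 16 of 32 down and 4 up (17 and 4 adjusted over the list alone). The median was -1.02 (adjusted p = 0.00172, and adjusted p = 0.158 with an estimated correlation). Apolipoproteins had 13 of 17 down and 1 up (14 and 1 adjusted over the list alone), with apobb.1 at -2.39 ± 0.39. The median was -1.42 (adjusted p = 0.000218, and adjusted p = 0.0588 with an estimated correlation). Leukocyte markers moved with these groups, 21 of 35 down and none up, also adjusted over the list alone, such as mpeg1.1 (-1.23 ± 0.22). The median was -0.88 (adjusted p = 0.000204, and adjusted p = 0.427 with an estimated correlation). So did markers of bile duct, endothelial and stellate cells, 22 of 40 down and none up (24 adjusted over the list alone), such as krt8 (-1.99 ± 0.44). The median was -0.56 (adjusted p = 1.31e-05, and adjusted p = 0.0965 with an estimated correlation). Intestinal markers were called low here too, with values given under other observations. Pancreatic genes had 8 of 30 down (2 adjusted over the list alone). The median was -1.10 (adjusted p = 0.00363, and adjusted p = 0.478 with an estimated correlation).

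Among metabolic lists, xenobiotic metabolism had 39 of 66 down and 1 up, also adjusted over the list alone, with cyp2ad3 at -2.89 ± 0.69. The median was -1.12 (adjusted p = 5.99e-09, and adjusted p = 0.116 with an estimated correlation). Amino acid catabolism had 42 of 61 down and 8 up (45 and 8 adjusted over the list alone), with bhmt (-3.93 ± 0.53) and agxtb (-3.59 ± 0.25) down. The median was -1.20 (adjusted p = 8.37e-08, and adjusted p = 0.116 with an estimated correlation). The growth hormone and IGF axis had 13 of 16 down and none up (13 and 1 adjusted over the list alone), with igf1 (-3.33 ± 0.53) and ghrb (-2.37 ± 0.23). The median was -2.15 (adjusted p = 3.93e-05, and adjusted p = 0.0588 with an estimated correlation). Glycolysis and gluconeogenesis had 21 of 39 down and 4 up (25 and 4 adjusted over the list alone), with gapdh at -2.61 ± 0.55. The median was -0.89 (adjusted p = 3.93e-05, and adjusted p = 0.143 with an estimated correlation). Fatty acid oxidation had 19 of 36 down and 3 up (23 and 3 adjusted over the list alone), with the uncoupling protein gene ucp1 at -4.38 ± 0.40. The median was -0.48 (adjusted p = 0.000475, and adjusted p = 0.212 with an estimated correlation), but 0.40 with median centring. Steroid hormone metabolism had 8 of 16 down and 1 up, also adjusted over the list alone. The median was -0.31 (adjusted p = 0.013, and adjusted p = 0.177 with an estimated correlation). Cholesterol synthesis was not called, with 4 of 26 up and 9 down. The median was -0.34 (adjusted p = 0.157), but 0.69 with median centring. The up share was 53.7%, against 86.8% with median centring, and with local backgrounds as deposited 1946 genes changed, fewer than at 24 h.

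**Figure D1:**
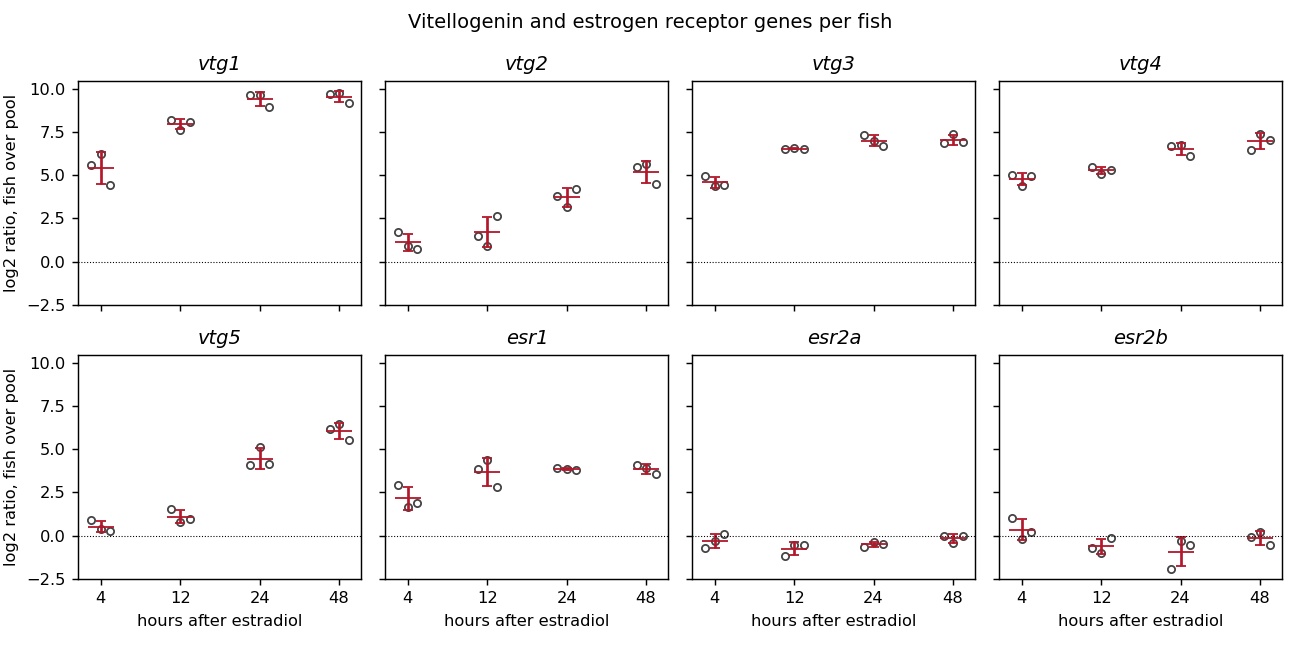
Log2 ratio of treated fish over the control pool (vertical axis) against hours after E2 (horizontal axis) for vitellogenin and estrogen receptor genes, with a point per fish, a short line at the mean of 3 fish and bars of 1 SD. The mean of vtg1 ran from 5.44 at 4 h to 9.57 at 48 h, that of vtg5 from 0.52 to 6.05, and that of esr1 from 2.16 to 3.87.

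Whether vitellogenin probes also bind other members of the family was not tested, so their values are uncertain between members, and the second probe of vtg3 varied widely between fish and passed at 48 h alone. The vtg genes on chromosome 22 were probed at 23098713 to 23098772 (vtg1), 23154183 to 23154336 (vtg4), 23118942 to 23119092 (vtg5), 23263847 to 23263906 (vtg2) and 23275622 to 23275681 (vtg8). The probe of vtg3 lay on chromosome 11 at 26103198 to 26104684 and that of esr1 on chromosome 20 at 27209514 to 27209573. The pool is the same RNA on every array, yet its unprocessed signal on the vtg4 probe averaged 157 at 4 h, 163 at 12 h, 1243 at 24 h and 1743 at 48 h, while that of the treated fish went from 7322 to 497000. On the vtg5 probe the pool signal went from 6254 at 4 h to 2433 at 48 h. On the rbp2a probe it went from 398 to 869. On the vtg2 probe it went from 82 to 123, close to the median Cy3 signal of all probes (92.22 to 104.1 per array). The fold of vtg2 therefore rests on a dim pool reading. Ratios of these genes rest on a pool reading that was not constant. Of the 3077 genes that differed between 4 and 48 h, 30 (0.975%) had a pool reading that moved by more than 1 on the log2 scale.

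**Figure D2:**
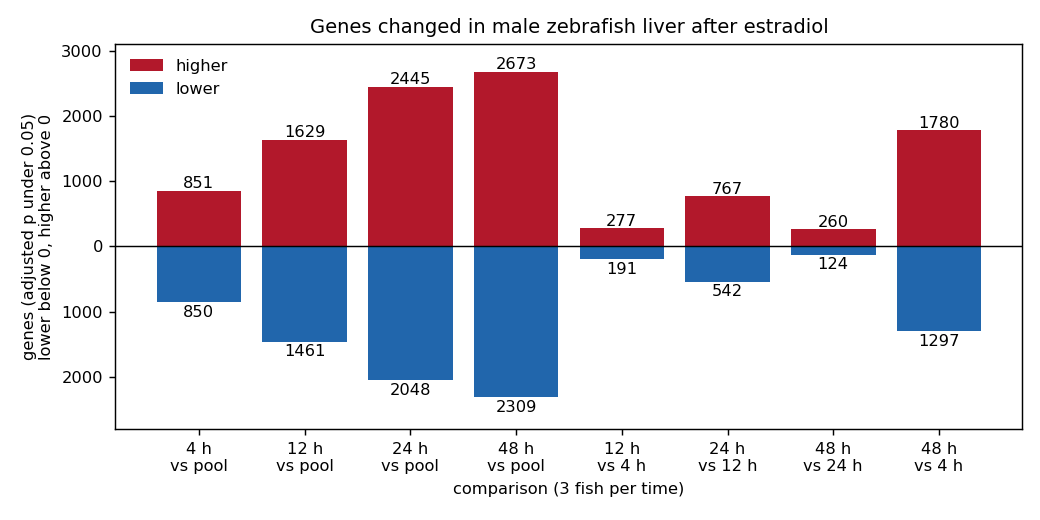
Number of genes (vertical axis, from 0) that were higher or lower, as bars, at each time against the control pool and between times, at adjusted p under 0.05 among 9176 genes. The bars against the pool grew from 851 up and 850 down at 4 h to 2673 up and 2309 down at 48 h.

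Differences between times were tested directly, which asked between which times each change appeared. Any difference in time of day is part of them, and the list of clock genes moved by a median of -0.40 from 4 to 12 h. From 4 to 12 h, DNA replication genes rose: mcm6 rose 29.8-fold (log2 4.90 ± 0.28, standard error, 3 against 3 fish, adjusted p = 2.3e-05), mcm3 24.8-fold (4.63 ± 0.25), cdca7a 24.7-fold (4.62 ± 0.32), the DNA methyltransferase gene dnmt1 23.7-fold (4.57 ± 0.74) and mcm4 12.4-fold (3.63 ± 0.29). The largest falls were rnasel3 (-5.16 ± 0.72), tdo2a (-3.21 ± 0.37), the efflux transporter gene abcc4 (-2.89 ± 0.43), hsd17b3 (-2.73 ± 0.49) and the clock gene per1b (-2.63 ± 0.18). These genes were also required to have no overlap between fish of the times compared, which chance alone gives in 10% of genes. In all 468 genes differed, 277 up and 191 down, 281 of them at least 2-fold. The DNA replication list had 28 of 54 up and none down (32 adjusted over the list alone). The median was 1.56 (adjusted p = 3.66e-29, and adjusted p = 0.469 with an estimated correlation). Within slide 1 it was 2.04, within slide 2 1.31 and with slide as a block 1.44. Pancreatic markers shifted by a median of 1.4 (adjusted p = 0.000105, and adjusted p = 0.658 with an estimated correlation), with 1 of 30 genes past the test, down. With median centring 290 genes differed and 26.2% of them were up, against 277 of 468, and with slide as a fixed block 240 differed. The count was 259 without 12 h fish 1, 234 without 12 h fish 3, 291 without 4 h fish 2, 205 without 4 h fish 3, 256 from the 6 arrays alone and 103 with local backgrounds as deposited.

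From 12 to 24 h, cholesterol synthesis genes rose steeply: fdps rose 74.3-fold (6.22 ± 0.42), hmgcs1 60.3-fold (5.91 ± 0.67), cyp51 41.5-fold (5.37 ± 0.80), msmo1 27.5-fold (4.78 ± 0.52) and ebp 22.6-fold (4.50 ± 0.51). The list had 17 of 26 up and none down (21 up and 1 down adjusted over the list alone). The median was 3.32 (adjusted p = 1.59e-17, and adjusted p = 0.0771 with an estimated correlation), 3.64 within slide 1, 3.17 within slide 4 and 3.31 with slide as a block. Proteasome subunits rose in 30 of 33 cases (32 adjusted over the list alone). The median was 1.05 (adjusted p = 1.88e-28, and adjusted p = 0.0246 with an estimated correlation), 1 within slide 1 and 1.1 within slide 4. Among the largest falls were ucp1 (-4.05 ± 0.43), the repressor gene nfil3-5 (-3.96 ± 0.35), ypel3 (-3.65 ± 0.27) and the heat shock cognate gene hsc70 (-3.48 ± 0.99). ER chaperones had 11 of 33 up and none down (16 up and 1 down adjusted over the list alone). The median was 0.59 (adjusted p = 8.88e-07, and adjusted p = 0.189 with an estimated correlation). Coagulation had 11 of 23 down (14 adjusted over the list alone). The median was -1.04 (adjusted p = 2.79e-09, and adjusted p = 0.138 with an estimated correlation), -0.84 within slide 1 and -1.09 within slide 4. Markers of bile duct, endothelial and stellate cells fell with it by a median of -0.40, 3 of 40 down (9 down and 1 up adjusted over the list alone, adjusted p = 0.00201, and adjusted p = 0.189 with an estimated correlation). Red cell markers fell too, by a median of -0.33, with 3 of 28 down and 1 up, also adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.527 with an estimated correlation). DNA replication rose in 21 of 54 (28 adjusted over the list alone). The median was 0.94 (adjusted p = 2.1e-11, and adjusted p = 0.345 with an estimated correlation), but the median was 0 within slide 1 and 2.25 within slide 4. Among vitellogenins vtg5 rose 10.4-fold (3.38 ± 0.33). In all 1309 genes differed, 767 up and 542 down, 621 at least 2-fold. With median centring 89.6% of the changed genes were up, against 58.6%. The count was 729 without 12 h fish 3, 849 without 24 h fish 2, 865 without 24 h fish 3, 852 from the 6 arrays alone and 609 with local backgrounds as deposited.

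From 24 to 48 h, the largest rises were in single genes: ccnb1 rose 23.3-fold (4.54 ± 0.74), cdc20 19.5-fold (4.28 ± 0.61), the kinetochore motor gene cenpe 15.3-fold (3.93 ± 0.64), ube2c 15-fold (3.91 ± 0.78) and the spindle gene tacc3 13.7-fold (3.77 ± 0.72). Their sizes differed by slide, with 5.89, 5.58, 5.14, 5.40 and 4.61 within slide 3 but 2.15, 2.77, 1.91, 1.49 and 1.59 within slide 4. The DNA replication and cell cycle list as a whole was not called (median -0.15, mean 0.67, adjusted p = 0.538), and 15 of its 54 genes rose and 6 fell (19 and 14 adjusted over the list alone). Cholesterol synthesis fell again, with cyp51 (-3.56 ± 0.80) and fdps (-3.15 ± 0.42) among 7 of 26 down (13 adjusted over the list alone). The median was -1.38 (adjusted p = 9.02e-06, and adjusted p = 0.386 with an estimated correlation), -0.90 within slide 3, -1.07 within slide 4 and -1.47 with slide as a block. Other falls were mhc2d8.35b2 (-4.10 ± 0.71), dio2 (-3.23 ± 0.63) and the AP-1 gene junbb (-2.90 ± 0.70). Complement had 2 of 22 down (10 adjusted over the list alone). The median was -0.67 (adjusted p = 1.39e-05, and adjusted p = 0.386 with an estimated correlation), -0.88 within slide 3 but -0.07 within slide 4. Leukocyte markers shifted with it by a median of -0.60 (adjusted p = 0.00031, and adjusted p = 0.67 with an estimated correlation), with none of 35 past the test, -0.33 within slide 3 and 0.12 within slide 4. In all 384 genes differed, 260 up and 124 down, 214 at least 2-fold. With median centring 190 differed and 81.6% were up, against 67.7%, and with slide as a fixed block 163 differed, without tacc3, ube2c, dio2 and junbb. The count was 140 without 24 h fish 1, 250 without 24 h fish 2, 148 without 48 h fish 1, 144 without 48 h fish 2, 135 from the 6 arrays alone, 674 with array weights and 10 with local backgrounds as deposited.

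Between 4 and 48 h, 3077 genes differed, 1780 up and 1297 down, 1626 at least 2-fold. The largest rises were kpna2 (239-fold, 7.90 ± 0.58), myl7, a myosin light chain of heart muscle (66-fold, 6.04 ± 0.69), the mitotic kinase gene cdk1 (63.1-fold, 5.98 ± 0.78), ccnb1 (62.6-fold, 5.97 ± 0.74) and ube2t (60.4-fold, 5.92 ± 0.57). The largest falls were cbln6 (-5.86 ± 0.80), dio2 (-5.36 ± 0.63), ucp1 (-4.71 ± 0.43), mhc1uea (-4.71 ± 1.55), whose probe switched between high and low at 48 h (-5.52, -5.49 and 0.02), and hsd17b3 (-4.26 ± 0.49). DNA replication and cell cycle had 51 of 54 up (52 adjusted over the list alone). The median was 3.33 (adjusted p = 3e-29, and adjusted p = 0.174 with an estimated correlation), 3.23 within slide 2 and 3.60 within slide 3. Proteasome subunits had 32 of 33 up (33 adjusted over the list alone). The median was 1.33 (adjusted p = 4.39e-24, and adjusted p = 0.0436 with an estimated correlation), 1.42 within slide 2 and within slide 3. ER translocation and export had 44 of 55 up and 1 down (47 and 1 adjusted over the list alone). The median was 1.18 (adjusted p = 3.19e-18, and adjusted p = 0.094 with an estimated correlation). Complement had 17 of 22 down, also adjusted over the list alone. The median was -1.38 (adjusted p = 3.9e-09, and adjusted p = 0.0638 with an estimated correlation), -1.79 within slide 2 and -1.65 within slide 3. Markers of other cells fell with it, leukocytes by a median of -0.64, 5 of 35 down (2 adjusted over the list alone, adjusted p = 0.00288, and adjusted p = 0.555 with an estimated correlation). Those of bile duct, endothelial and stellate cells fell by -0.40, 8 of 40 down, also adjusted over the list alone (adjusted p = 0.00196, and adjusted p = 0.176 with an estimated correlation). Red cell markers, at -0.43, were not called (adjusted p = 0.128) except with slide as a block (adjusted p = 0.0187). With median centring 67.1% of the changed genes were up, against 57.8%. With local backgrounds as deposited 1063 genes differed.

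Across the 4 times together 3423 genes differed in limma's F-test, 1901 of them by at least 2-fold between a pair of times, and 1386 differed with local backgrounds as deposited. Treating slide as a random block gave 506, 1396, 424 and 3153 genes for the 4 comparisons between times and 3529 for the F-test, and as a fixed block 940 from 12 to 24 h, 2747 between 4 and 48 h and 2840 for the F-test. Against the pool, 438 genes were up at all 4 times and 276 down, and 461 of these 714 did not differ among the times. Of the 6688 genes that changed at 1 or more times, 452 changed in opposite directions at 2 times. Of the set tests with a preset correlation, the proteasome calls from 12 to 24 h and between 4 and 48 h held with an estimated correlation and none of the others did. By fry, 13, 20, 31 and 32 of the 38 lists moved on balance one way at 4, 12, 24 and 48 h, and 32, 36, 37 and 38 had genes that changed in either direction, neither of which compares a list with other genes.

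**Figure D3:**
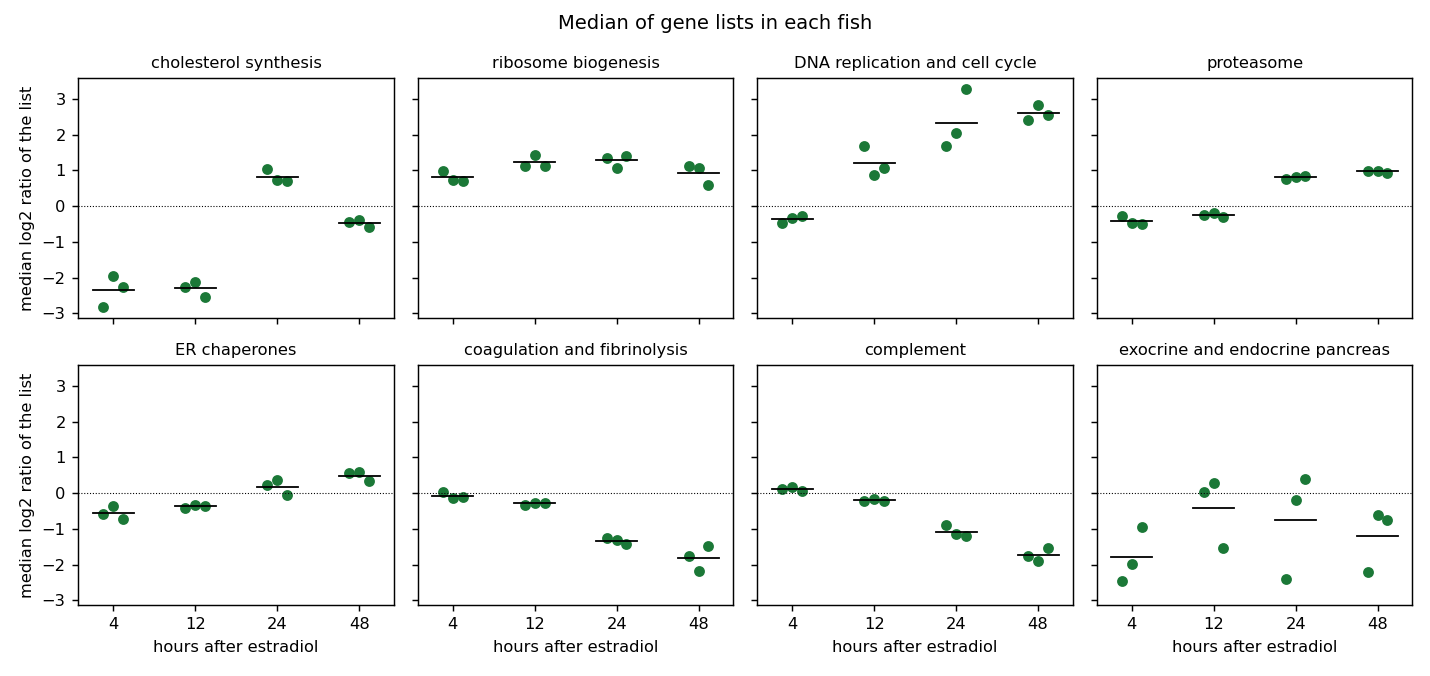
Median log2 ratio to the control pool (vertical axis) of gene lists in each of the 12 fish, as points with a line at their mean, against hours after E2 (horizontal axis). In the fit, the cholesterol list had medians of -2.40 at 4 h, -2.54 at 12 h and 0.74 at 24 h, DNA replication ran from -0.40 at 4 h to 2.65 at 48 h, and pancreatic markers ranged from -2.45 to 0.39 between single fish.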

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

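The tests of on and off probes, of gene lists between times, of pancreatic genes and of a constant dye or pool offset were chosen only after the result was seen, while the splits of the arrays and the test of duplicate genes were planned. Between 4 and 12 h 468 genes differed, between 12 and 24 h 1309, between 24 and 48 h 384 and between 4 and 48 h 3077, and 3423 differed among the 4 times. Gene lists called between those times numbered 15, 22, 16 and 25.

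Rises from 4 to 12 h were largest for mcm6 (4.90), mcm3 (4.63), cdca7a (4.62), dnmt1 (4.57) and mcm4 (3.63), and falls for rnasel3 (-5.16), tdo2a (-3.21), abcc4 (-2.89), hsd17b3 (-2.73) and per1b (-2.63). From 12 to 24 h fdps (6.22), hmgcs1 (5.91), cyp51 (5.37), msmo1 (4.78) and ebp (4.50) rose, and ucp1 (-4.05), nfil3-5 (-3.96), ypel3 (-3.65) and hsc70 (-3.48) fell. From 24 to 48 h ccnb1 (4.54), cdc20 (4.28), cenpe (3.93), ube2c (3.91) and tacc3 (3.77) rose, and mhc2d8.35b2 (-4.10), cyp51 (-3.56), dio2 (-3.23), fdps (-3.15) and junbb (-2.90) fell. Between 4 and 48 h kpna2 (7.90), myl7 (6.04), cdk1 (5.98), ccnb1 (5.97) and ube2t (5.92) rose, and cbln6 (-5.86), dio2 (-5.36), ucp1 (-4.71), mhc1uea (-4.71) and hsd17b3 (-4.26) fell.

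Lists called in opposite directions against the pool differed between the times by medians of 1.56 for DNA replication from 4 to 12 h, 1.05 for the proteasome and 3.32 for cholesterol synthesis from 12 to 24 h, and, between 4 and 48 h, 1.26 for ER chaperones, 1.18 for ER translocation, 3.33 for DNA replication and 1.33 for the proteasome. With an estimated correlation the proteasome differences passed (adjusted p = 0.0246 and 0.0436), and the others did not, at 0.469 and 0.0771 up to 24 h and 0.164, 0.094 and 0.174 between 4 and 48 h. The fall of DNA replication at 4 h was not called with local backgrounds as deposited (-0.11). With median centring the proteasome list stood above 0 at 4 and 12 h and ER translocation above 0 at 4 h (0.37, 0.21 and 0.52). None of these was called with that centring, so these reversals hold for the loess values.

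Among 100 splits of the 12 arrays into 4 groups of 3, 1, the real one, gave as many as 3423 genes, and the highest other gave 471, so a random grouping is excluded for the F-test. For differences between times 6 arrays make 10 splits, too few for a share under 0.05. The real split gave 468, 1309, 384 and 3077 genes and the highest others 2, 0, 5 and 1, so 1 of 10 splits was as large each time. For lists the real counts were 15, 22, 16 and 25 and the highest others 13, 22, 18 and 26, so 1, 2, 2 and 2 splits were as large.

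Pancreatic genes were low at 4 h, with array medians of -2.45, -1.98 and -0.95 there and from -2.41 to 0.39 at the other times. A candidate explanation is that different amounts of pancreatic tissue were taken along with the livers, and the SD of the list between fish of the same time was 5.85 times that of the typical list. A fall in all pancreatic tissue at 4 h stays open, since 6938 of 15400 exact splits gave differences among the times as large (p = 0.451).

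Of 22035 probes, 54 switched between high and low in fish of the same time (SD over 2), from 31 genes with a proper symbol. Among these were ctsba, rnasel2, c3b.2, mhc1uba, mhc2dga, mhc1uea and the probe assigned to tapbp.1. Of 26 probes of MHC, peptide-loading and related genes, 6 (23.1%) switched, against 0.245% of all probes. Sequence variants under single probes may be behind some of the 54, since in 64.7% of genes with another probe (11 of 17) the brightest other one did not follow. In the rest it did, with correlations of 0.96 for cyp24a1, 0.97 for slc27a1b and 1 for apcs and mhc1uba. Among the 11, a further probe of rpl36 did follow, but it starts at 14695, close to 14705 of the first, so it is hardly a separate reading. The other probe of ctsba switched in the opposite sense (correlation -0.76). Neither observation decides for or against sequence variants. The 11 also include tapbp.1, whose switching probe may read another gene. Defects of single spots stay open for the whole set, with a median correlation of 0.25 between both probes. No biological explanation was tested.

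More genes changed against the pool at later times, except that with local backgrounds as deposited the count fell from 3618 at 24 h to 1946 at 48 h. A constant dye bias or a peculiarity of the pool is excluded as the whole cause, since 53.1% of the genes changed at 48 h (2645 of 4982) also differed from 4 h in the same direction. For 461 of the 714 genes changed one way at all 4 times without a difference among them, such an offset and an early response cannot be told apart, as no dye swap or second pool was run.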

How the results depend on the processing

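Local backgrounds replaced above 5 times the median and camera between times were chosen only after the result was seen, and the other tests here were planned. Normexp on local backgrounds as deposited was the planned main setting and became an alternative after the data were seen. The design has 3 fish per time, 1 pool, no dye swap and no controls at the later times. Background replacement was chosen after the planned correction had been seen to follow high local backgrounds beside some spots, whose cause was not tested. The pool reading itself moved on vitellogenin and rbp2a probes, so fold sizes there are less certain than directions. Where a value depends on a setting, the cause was not tested.

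Normexp on local backgrounds as deposited gave 658 genes at 4 h, 1892 at 12 h, 3618 at 24 h and 1946 at 48 h, so that the count did not rise from 24 to 48 h, and 103 between 4 and 12 h, 609 between 12 and 24 h, 10 between 24 and 48 h, 1063 between 4 and 48 h and 1386 in the F-test. The difference between 24 and 48 h rests most on this choice, with 384 genes when backgrounds were replaced. At least 2-fold changes numbered 458, 1008, 1753 and 2006 at the 4 times, 281, 621, 214 and 1626 between times and 1901 in the F-test. Median centring without loess gave 3702 genes at 4 h, 290 between 4 and 12 h and 190 between 24 and 48 h. Only the arrays compared gave 846 genes at 4 h, 256 between 4 and 12 h, 852 between 12 and 24 h and 135 between 24 and 48 h. Slide as a fixed block gave 240 between 4 and 12 h and 163 between 24 and 48 h. For 24 and 48 h, Agilent processed signals gave 220, series values 216 and array weights 674. Over all settings with 12 fish or only the arrays compared the counts ran from 458 to 3702 at 4 h, 1008 to 3138 at 12 h, 1753 to 4768 at 24 h, 1946 to 5543 at 48 h, 103 to 506, 609 to 1396, 10 to 674 and 1063 to 3468 between times, and 1386 to 3695 in the F-test. A linear trend on log time called 2879 genes.

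Camera with an estimated correlation called 0 lists at 4 h, 0 at 12 h, 0 at 24 h and 0 at 48 h, against 14, 16, 27 and 30 with the preset one. Fry called 13, 20, 31 and 32, and fry in either direction 32 at 4 h, 36 at 12 h, 37 at 24 h and 38 at 48 h. Slide as a fixed block gave 14, 19, 28 and 31 lists.

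With median centring 81 list medians and gene values changed sign, all from below 0 to above it. Counted as reversed were 23 results, where the sign of a gene, or the direction of a list's test against other genes, changed and the result had passed before or passed now. These were amy2al1 at 48 h (0.55), copa at 4 h (0.10), esr2a at 24 h (0.23) and 48 h (0.59), hpda at 24 h (0.36) and 48 h (0.05), hsd17b4 at 4 h (0.23), itih2 at 24 h (0.22), ndufs1 at 4 h (0.54), psma4 (0.02) and psma8 (0.05) at 12 h, psma6a (0.02), psmc6 (0.24), psmd4a (0.07) and sec11a (0.27) at 4 h, and ttr at 24 h (0.43) and 48 h (0.05). Of the lists, ER translocation (0.52), amino acid catabolism (0.62) and proteasome (0.37) at 4 h and oxidative phosphorylation (0.38) and proteasome (0.21) at 12 h turned up, and translation, at 0.02 at 4 h, moved to 0.82.

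Leaving out each fish in turn gave 978 to 1744 genes at 4 h, 2145 to 3171 at 12 h, 3540 to 4525 at 24 h and 3781 to 4996 at 48 h, 205 to 548, 729 to 1273, 140 to 366 and 2312 to 3124 between times, and 2782 to 3310 in the F-test. Counts moved by over 1.5 times at 4 h without 4 h fish 1 (978) or fish 2 (984), from 4 to 12 h without 12 h fish 1 (259) or 3 (234) or 4 h fish 2 (291) or 3 (205), from 12 to 24 h without 12 h fish 3 (729) or 24 h fish 2 (849) or 3 (865), and from 24 to 48 h without 24 h fish 1 (140) or 2 (250) or 48 h fish 1 (148) or 2 (144). Lists called stayed within 14 to 15, 16 to 20, 26 to 28 and 29 to 31 at the 4 times.

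The labels number the fish 1 to 3 at each time. Deviations of fish with the same number had correlations of -0.125 to 0.214 with a median of 0.0221 over 18 pairs, 5 of them over 0.1. Pairs with other numbers reached 0.157, and 9 of 12 arrays correlated best with an array of their own number. The number that chance alone gives was not worked out. Slide 1 held only fish 1 and slide 4 only fish 3, so fish number and slide cannot be told apart there. A replicate block gave 1708, 3121, 4508 and 4989 genes at the 4 times, 425, 1244, 357 and 3075 between times and 3389 in the F-test.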

Other observations

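The tests of lists and of duplicate genes in this part were planned, and only the reading of the pool's own signal was chosen after the result was seen. Clock genes were lower from 12 h on, with 19 of 34 down and 5 up at 12 h (19 and 7 adjusted over the list alone, median -0.49, adjusted p = 0.00105, and adjusted p = 0.171 with an estimated correlation), 15 down and 3 up at 24 h (17 and 3 adjusted over the list alone, median -0.38, adjusted p = 0.00209, and adjusted p = 0.114 with an estimated correlation) and 16 down and 7 up at 48 h (17 and 7 adjusted over the list alone, median -0.39, adjusted p = 0.0135, and adjusted p = 0.158 with an estimated correlation). At 12 h per1b was at -2.92 ± 0.22 and bhlhe40 at -3.45 ± 0.38, and at 48 h cry3b at -2.71 ± 0.19. At 4 h the list was not called (median -0.03), and time of day was not modelled. Oxidative phosphorylation had 37 of 64 genes up and 4 down at 48 h (41 and 4 adjusted over the list alone, median 0.38, adjusted p = 1.83e-05, and adjusted p = 0.22 with an estimated correlation), with cox6a1 at 1.70 ± 0.16. At 4 h it had 2 up and 1 down (none adjusted over the list alone, median 0.15, adjusted p = 0.036, and adjusted p = 0.772 with an estimated correlation, a call lost without fish 3 at 0.08), and at 12 and 24 h it was not called, with medians of -0.10 (0.38 with median centring) and 0.15.

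Regulators of the unfolded protein response were called at 48 h alone, 10 of 23 up and 4 down (12 and 4 adjusted over the list alone, median 0.44, adjusted p = 0.0483, and adjusted p = 0.232 with an estimated correlation), although xbp1 was at 3.37 ± 0.17 from 4 h and 2.82 ± 0.21 at 48 h, and the medians before were -0.31, -0.42 and 0.27. Thyroid hormone genes had 4 of 5 down at 24 h (5 adjusted over the list alone, median -0.77, adjusted p = 0.0313, and adjusted p = 0.122 with an estimated correlation) and 5 down at 48 h, also adjusted over the list alone (median -0.99, adjusted p = 0.00494, and adjusted p = 0.0906 with an estimated correlation), though the 24 h median was -0.25 and not called and ttr turned to 0.43 and 0.05 with median centring, and medians of -0.14 and 0.30 at 4 and 12 h were not called. Immediate early genes fell at 48 h, 19 of 46 with 4 up, also adjusted over the list alone (median -0.38, adjusted p = 0.0049, and adjusted p = 0.311 with an estimated correlation), with junbb at -4.53 ± 0.32, after medians of -0.09, -0.29 and -0.02. Inflammation and interferon genes had 13 of 44 down and 1 up at 24 h (11 and 1 adjusted over the list alone, median -0.33, adjusted p = 0.0484, and adjusted p = 0.545 with an estimated correlation, but 0.04 with median centring) and 17 down at 48 h (16 adjusted over the list alone, median -0.61, adjusted p = 0.00101, and adjusted p = 0.314 with an estimated correlation), with socs1a at -3.47 ± 0.46, after -0.16 and -0.09. The 24 h call was lost without fish 2 (median -0.25) or fish 3 (-0.22). Leukocyte markers moved with this list at 48 h, with array medians of -0.92, -1.13 and -0.31 against -0.81, -0.62 and -0.33 for inflammation and interferon genes.

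Bile acid genes had 6 of 14 down at 24 h (7 adjusted over the list alone, median -0.35, adjusted p = 0.00925, and adjusted p = 0.114 with an estimated correlation, but 0.02 with median centring) and 7 down and 1 up at 48 h, also adjusted over the list alone (median -0.35, adjusted p = 0.0199, and adjusted p = 0.155 with an estimated correlation), with cyp8b1.1 at -2.71 ± 0.34, after -0.25 and -0.34. Sexually dimorphic and lipid transport genes had 9 of 16 down at 24 h (10 adjusted over the list alone, median -0.78, adjusted p = 0.00155, and adjusted p = 0.123 with an estimated correlation, but 0.19 with median centring) and 9 down and 1 up at 48 h (10 and 1 adjusted over the list alone, median -0.82, adjusted p = 0.0063, and adjusted p = 0.173 with an estimated correlation, but -0.03 and not called with median centring), after -0.03 and -0.45. Cytosolic heat shock genes were called at 24 h, 13 of 29 up and 3 down (14 and 4 adjusted over the list alone, median 0.40, adjusted p = 0.0246, and adjusted p = 0.367 with an estimated correlation), but not without fish 1 (0.32), with -0.06, -0.10 and -0.11 at the other times. Acute phase genes at 24 h had 11 of 32 down and 4 up, also adjusted over the list alone (median -0.74, adjusted p = 0.0346, and adjusted p = 0.315 with an estimated correlation), but 0.32 with median centring. Intestinal markers had 6 of 15 down and 1 up at 24 h, also adjusted over the list alone (median -0.58, adjusted p = 0.0313, and adjusted p = 0.309 with an estimated correlation, but -0.17 without fish 3), and 7 down and 2 up at 48 h, also adjusted over the list alone (median -0.82, adjusted p = 0.0388, and adjusted p = 0.294 with an estimated correlation, a call lost without fish 2).

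Lists not called at any time had medians at 4, 12, 24 and 48 h of 0.27, 0.03, -0.05 and 0.03 for steroid receptors, where ar was at 1.54 ± 0.53 at 4 h, of -0.07, -0.11, -0.38 and -0.67 for retinoid metabolism, of -0.08, -0.32, -0.25 and -0.34 for fatty acid synthesis, where dgat2 was at -2.65 ± 0.26 at 48 h, of -0.06, -0.22, -0.22 and -0.09 for antioxidant enzymes, where cat was at -2.41 ± 0.29 at 48 h, and of 0.03, 0.07, 0.12 and -0.16 for testis markers. With median centring the medians below 0 turned above it for fatty acid synthesis and antioxidant enzymes at all 4 times, for retinoid metabolism at 4 and 24 h, for steroid receptors at 24 h and for testis markers at 48 h. Egg envelope proteins had too few tested genes for a list test, with zp3b at 0.41 ± 0.21 and zp3d.2 at -0.30 ± 0.19 at 48 h. List median, mean and test differed in sign only in lists that were not called, such as thyroid genes at 4 and 12 h and DNA replication between 24 and 48 h.

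Among 784 pairs of duplicate genes named a and b, 147 changed in the same direction at 48 h, 63 in opposite directions, 385 in 1 member and 189 in neither. Random pairings gave means of 104 and 103, and p = 1e-04 by permutation for as few opposite pairs is the smallest that 10000 pairings can give. The widest gaps included slc43a1a at 4.66 with slc43a1b at -4.85 and apoea at 2.96 with apoeb at -2.30. The pool's own log2 signal shifted between 4 and 48 h by 3.91 on vtg4, 1.78 on vtg3, 1.49 on rbp2a, 1.38 on vtg1, 1.14 on vtg2 and -1.07 on vtg5, against a median absolute shift of 0.0918 over the 3077 genes that differed, and of the 30 genes with a pool shift over 1, 19 moved in the direction of the fish.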
